A study of Mus musculus with 4 samples.

How the data were processed

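Spleen and bone marrow cells of 24-month-old BL/6 mice were profiled by droplet single-cell RNA sequencing with 10x Genomics 3' chemistry and cell multiplexing. Per the labels, mice received MDL-800 at 75 mg/kg or 100 uL of DMSO vehicle, both intraperitoneally, and red cells were lysed before capture. How long treatment lasted and how many animals went into each library are not given in the sources used here. The 4 libraries made 4 groups of 1 library each: vehicle spleen, MDL-800 spleen, vehicle bone marrow and MDL-800 bone marrow. The libraries of a tissue shared 1 droplet run, in which each library carried 2 of the 4 multiplexing tags. What a tag marks (an animal, or a split of 1 suspension) is not given in the sources used here, so values per tag are given as spread within a library and not as replicates.

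The authors deposited raw UMI counts, 1 table per library, for 32285 genes and 12 multiplexing tags. Per the submitters' processing notes, Cell Ranger and Seurat 4.3.0 were used with the mm10 genome. The Cell Ranger version is not given in the sources used here. The deposited run metrics name a multi-sample run with cell calling and assignment by tag, so the deposited counts cover called cells with an assigned library only. Nothing normalised was deposited in the tables used here. Per the metrics, 70.98% and 72.51% of reads in the vehicle and MDL-800 spleen libraries mapped to the transcriptome and 53.98% and 56.75% to exons, so reads in introns were counted as well. The corresponding shares in bone marrow were 78.78% and 80.85% for the transcriptome and 65.73% and 69.53% for exons. Of the barcodes called as cells, 8.4% in the spleen run and 7.77% in the bone marrow run were multiplets by tag and had been left out before deposit.

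The called cells numbered 4969 and 4139 in the vehicle and MDL-800 spleen libraries and 4962 and 4669 in the bone marrow libraries. Cells with at least 200 genes and at most 10% mitochondrial UMIs were kept. Scrublet, through Scanpy, called between 0.193% and 0.789% of cells per library. Calls were to be left out unless they covered under 0.5% of a library's cells. That was the case in all libraries but vehicle spleen. Its 32 calls were kept as well, so that the libraries were treated alike, although the rule applied library by library would have left them out. Removing them was tried as an alternative. Counts were scaled to 10000 per cell and log-transformed. The 2 libraries of a tissue were then clustered together on 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1. Immunoglobulin and T cell receptor variable segments, sex-linked genes and mitochondrial genes were kept out of the variable genes. Each cluster was scored against 21 marker sets, as the share of its cells with each marker less that share in the other clusters. It took the best class with at least 3 markers found in at least 10% of its cells. A cluster stayed unnamed when its 10 leading genes held more markers of another class, or when no class qualified. Neutrophil lineage clusters were further divided into precursor and mature clusters by their markers.

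Class shares are given with exact (Clopper-Pearson) 95% binomial intervals, and differences in share with Newcombe intervals. For gene levels, raw UMIs were summed per gene over all cells of a library and over each class with at least 100 cells in both libraries of the tissue. Folds are MDL-800 over vehicle, each sum divided by the UMIs of that class and library, with the exact conditional binomial interval of a ratio of Poisson counts. A group at 0 UMIs was set to a floor of 3 counts over the group, which makes the fold a lower bound. Intervals and floors cover counting error only and say nothing of how animals vary. With 1 library per group, no test between treatments was possible within a tissue. A fit over both tissues with tissue as a term would leave 1 residual degree of freedom and was not run, and no p-value or number of differing genes is given.

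The choice of classes, filters, gene lists, named genes and most alternatives was made before the data were examined. The named genes were Sirt6 first. For all cells and for the 3 largest classes of each tissue, they were then the 5 genes with the highest and the 5 with the lowest fold among genes with at least 100 UMIs over both libraries. That ranking left out variable receptor segments, immunoglobulin constant genes outside B and plasma cells, sex-linked, hemoglobin, mitochondrial and predicted genes, ribosomal pseudogenes and markers of other classes. Up to 2 members each way with at least 50 UMIs were named in a gene list that is described. A gene that this rule names in spleen T cells and a small spleen B cell cluster are not reported here. The same ranking in mature neutrophils alone was added after the data were seen.

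The 28 gene lists covered sirtuins, glycolysis, NF-kB targets, senescence and secretory factors, inflammatory cytokines and receptors, type I interferon response, MHC class II, MHC class I, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, immediate early genes, heat shock and chaperones, and cell cycle. They also covered DNA repair, antioxidant response, autophagy and lysosome, fatty acid oxidation, naive T cell genes, activated and exhausted T cell genes, age-associated B cell genes, immunoglobulin constant regions, neutrophil granule genes, neutrophil maturation genes, the TGF-beta pathway, histone and chromatin enzymes, hemoglobin and red cell genes, and sex-linked genes. A list's value is the median log2 fold of its members with at least 20 UMIs, with 0.5 UMI added to each sum, for lists with at least 5 such members. Each median was placed among 10000 random lists of the same size matched on expression, as a description of these libraries, and given a 95% counting interval from 500 Poisson resamples.

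Totals were the main scaling. TMM factors (edgeR 4.0.16) and median-of-ratios size factors (DESeq2 1.42.0) were alternatives, used for scaling only. Where TMM moved the median of all genes by more than 0.1 log2, list medians are given after TMM scaling. Other alternatives were no cell filter, a stricter filter of at least 500 genes and at most 5% mitochondrial UMIs, Leiden resolutions 0.5 and 2, classes from markers alone, all 4 libraries clustered together, cells thinned to 1000 UMIs, each cell weighted equally, minimums of 10 and 500 UMIs, 2 UMIs added, and list means.

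The calculation was tested on simulated data with 200 of the genes altered by known folds. For spleen B cells (8855 genes), simulated folds of 1.5, 2, 4 and 0.25 came back as medians of 1.49, 1.97, 3.93 and 0.245. Of the intervals, 92% to 98% held the true fold. The simulated class sums were Poisson draws, the model that the intervals assume, so this coverage checks the calculation only. Cells were not simulated, so coverage for genes whose UMIs lie in few cells was not tested. Gene symbols and IDs are those of the count tables. Positions come from GENCODE M21 (GRCm38, the assembly also called mm10), in which 32158 of the 32285 IDs were found, and are counted from 1. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Scanpy 1.11.5, igraph 0.11.9, scikit-learn 1.9.0, Matplotlib 3.10.9 and R 4.3.3 were used.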

Results

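MDL-800 binds SIRT6 away from its active site and raises its activity. SIRT6 is an NAD-dependent enzyme that removes acetyl and longer acyl groups from histones, and it restrains genes of glycolysis and NF-kB signalling. The libraries hold single cells of the spleen and bone marrow of 24-month-old mice given MDL-800 or DMSO vehicle. Both organs hold immune cells, and the bone marrow also makes them. Each of the 4 groups (vehicle or MDL-800, spleen or bone marrow) was 1 library, so there are no replicates and no difference between treatments was tested. Intervals cover counting error only. Each library carried 2 multiplexing tags, and values per tag show the spread within a library.

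After filtering, 4058 vehicle and 3150 MDL-800 spleen cells were kept, with 19489888 and 19817308 UMIs. The bone marrow libraries kept 4672 vehicle and 4240 MDL-800 cells, with 23202482 and 28677816 UMIs. Cells of the MDL-800 libraries were deeper in both tissues. The median was 3950 UMIs per cell in the vehicle and 4893 in the MDL-800 spleen library, and 3321.5 and 4957.5 in bone marrow. More than 10% mitochondrial UMIs were found in 18.3% of called cells of the vehicle spleen library and in 23.8% of the MDL-800 spleen library, and in 5.82% and 9.19% in bone marrow. The libraries of a tissue shared 1 droplet run, and so the same free RNA.

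The first question in the spleen was whether its cell types made up different shares of the library with MDL-800. Cells made by the myeloid branch of blood formation were a larger share of the MDL-800 library, and B cells a smaller one. Neutrophils, which engulf bacteria and normally leave the bone marrow only when mature, stood at 5.50% (4.81% to 6.24%) in the vehicle and 12.3% (11.2% to 13.5%) in the MDL-800 library. Most of that difference was in neutrophil precursors, the immature stage that fills granules with proteins such as Ngp, Camp and Ltf. Precursors were 0.641% (0.419% to 0.937%) of vehicle cells and 6.63% (5.79% to 7.56%) of MDL-800 cells, 26 and 209 cells. The tags gave 0.479% and 0.812% in the vehicle library and 6.10% and 7.27% in the MDL-800 library. Mature neutrophils were 4.85% and 5.65%, and the interval of that difference held 0 (-0.236 to 1.86 percentage points). With all 4 libraries clustered together, the difference was 2.86 for mature neutrophils and 3.81 for precursors, against 5.99 for precursors here. Monocytes were 2.86% of vehicle and 6.06% of MDL-800 cells, a difference of 3.20 percentage points (2.24 to 4.21). That held in both kinds, the classical cells with F13a1 and Fn1 (1.82% and 3.52%) and the patrolling cells with Ace and Adgre4 (1.03% and 2.54%). Plasma cells, which secrete antibody, were 2.37% and 3.94%, a difference of 1.57 percentage points that was 0.964 from markers alone and 1.04 (-0.0146 to 2.14) with at least 500 genes and at most 5% mitochondrial UMIs.

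B cells were 58.2% (56.7% to 59.7%) of the vehicle spleen library and 50.5% (48.7% to 52.2%) of the MDL-800 library, a difference of -7.73 percentage points (-10.0 to -5.41). Without the cell filter it was -3.86 (-5.91 to -1.80). The tags did not overlap, with 55.9% and 60.4% against 48.6% and 52.0%. A B cell cluster with Bhlhe41, a transcription factor of the B-1 cells that make natural antibody, and Sox5, a gene of age-associated B cells, was 7.93% and 3.87%. The larger of the clusters with the follicular B cell genes Fcer2a and Ighd was 22.6% and 19.0%, a difference of -3.53 percentage points that was -6.76 with at least 500 genes and at most 5% mitochondrial UMIs. The smaller was 4.78% and 4.0%, with an interval that held 0 (-1.72 to 0.183). Marginal zone B cells, marked by Cr2 and Dtx1, were 11.0% and 11.8%, with an interval of the difference that held 0, but not at Leiden resolution 2 (1.80, 0.523 to 3.10) or with all 4 libraries clustered together (2.89, 1.37 to 4.44).

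T cells were 19.1% and 18.7% of the spleen libraries, a difference whose interval held 0 (-2.19 to 1.46 percentage points). That class did not hold all cells with T cell genes. A cluster that met no class by the naming rule had Cd3d in 96.8%, Cd8a in 67.0% and Nkg7 in 97.4% of its cells, with the killer receptor genes Klre1 and Klrk1 among its leading genes. It was 6.31% of the vehicle and 1.78% of the MDL-800 library, a difference of -4.53 percentage points (-5.42 to -3.65). When cells were classed from markers alone the T cell difference was -4.05 percentage points, and when cells were thinned to 1000 UMIs it was -3.77. Conventional dendritic cells (2.56% and 2.76%) and macrophages (0.370% and 0.286%) had intervals that held 0. With at least 500 genes and at most 5% mitochondrial UMIs, the macrophage difference was -0.358 percentage points (-0.725 to -0.00139).

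**Figure D1:**
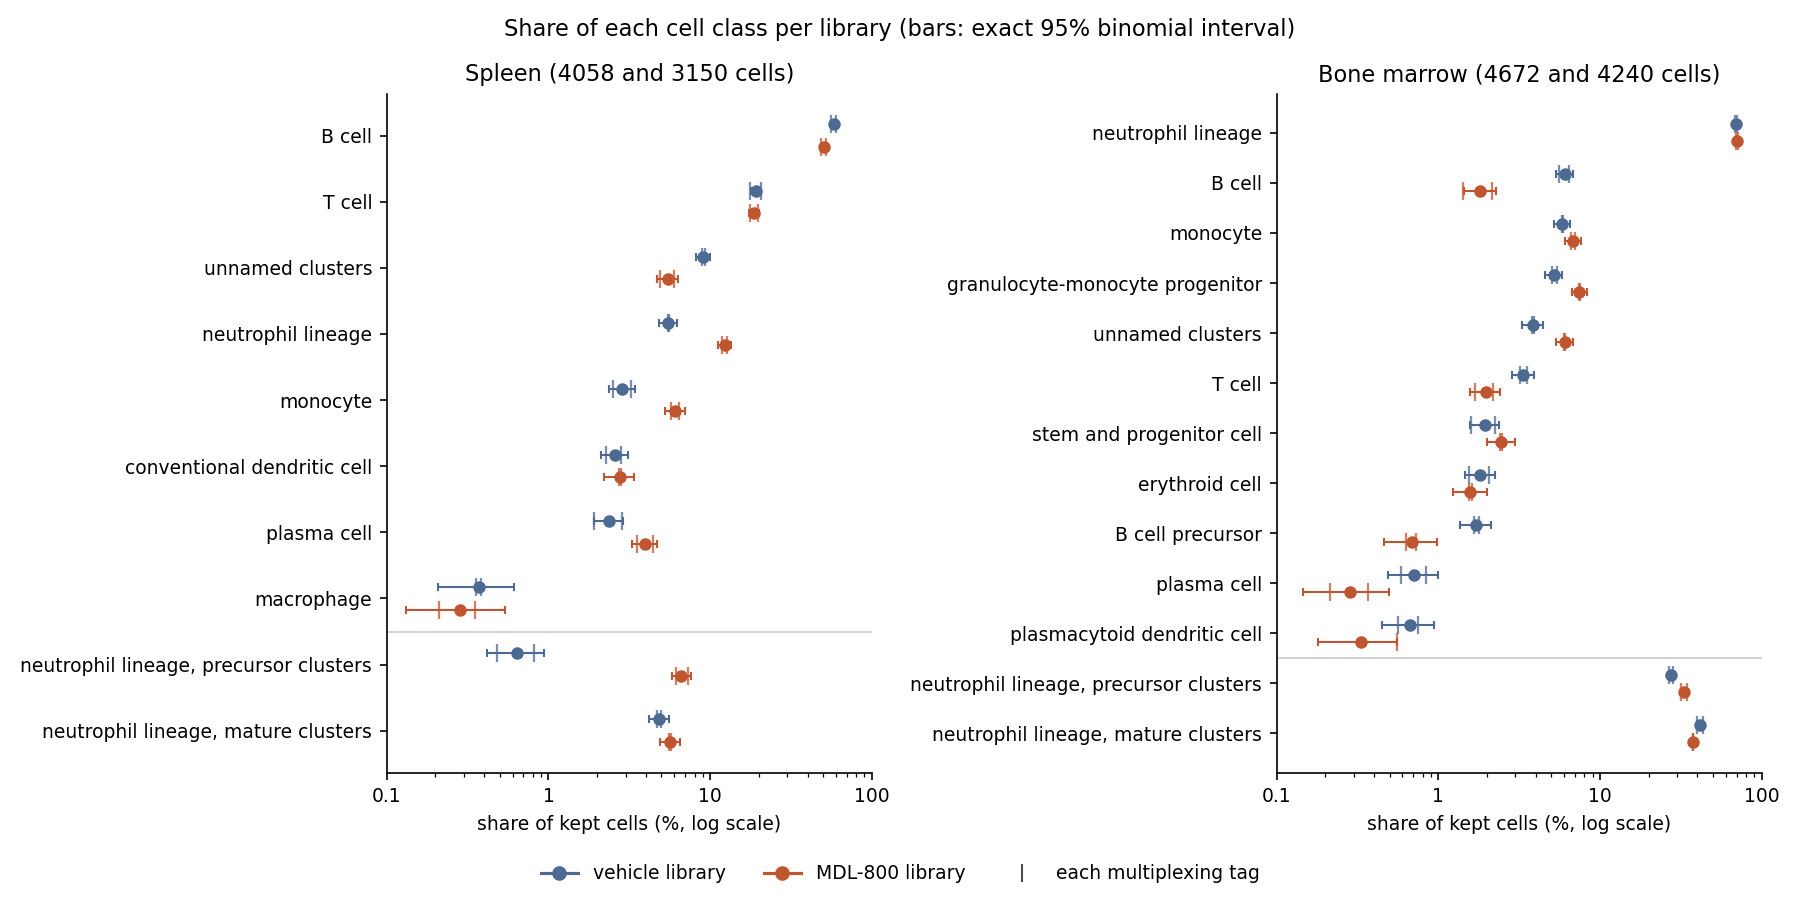
Share of kept cells per class (percent, log axis) in the vehicle and MDL-800 libraries of spleen and bone marrow, with exact 95% binomial bars and a tick for each multiplexing tag within the axis. Spleen neutrophil precursors stand apart at 0.641% and 6.63%, and bone marrow B cells at 6.04% and 1.82%.

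The next question was how gene levels differed in the spleen, beginning with the target of the drug. Sirt6 (ENSMUSG00000034748, GRCm38 chromosome 10, 81621785 to 81627797) encodes SIRT6. It had 81 UMIs in the vehicle spleen library and 68 in the MDL-800 library, or 4.16 (3.30 to 5.17) and 3.43 (2.66 to 4.35) UMIs per 1000000. The fold was 0.826 (0.589 to 1.15), so no difference was detectable at this depth. In B cells the fold was 1.09 (0.684 to 1.73) and in T cells 0.954 (0.403 to 2.22). MDL-800 acts on the protein, and activity was not measured. The 7 sirtuins had a median log2 fold of -0.20, within the central 95% of random lists.

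Over all spleen cells, genes of cell division and of neutrophils were higher in the MDL-800 library and genes of naive T cells lower, the direction of the class shares for neutrophils. Cell cycle genes were higher in the MDL-800 library in 29 of 29 members, with a median log2 fold of 1.08 (0.96 to 1.22). Cdk1, the kinase that starts mitosis, was 3.85-fold higher (3.18 to 4.68) and Rrm2, which makes DNA building blocks, 3.79-fold (3.12 to 4.63). Neutrophil granule genes had a median of 1.83, with Ngp at 11.8-fold (11.5 to 12.2) and Camp at 11.0-fold (10.8 to 11.2). Neutrophil maturation genes stood at 0.61, with Retnlg at 4.40-fold. Glycolysis genes were higher in 15 of 18, with a median of 0.47, led by the lactate exporter Slc16a3 (1.75-fold, 1.52 to 2.02). The antioxidant list stood at 0.25, with the heme-degrading enzyme Hmox1 at 3.80-fold (3.07 to 4.73). The senescence list stood at 0.27, with Mmp9, a protease stored in neutrophils, at 2.82-fold and the T cell chemokine Ccl5 at 0.578-fold. Lower in the MDL-800 library were naive T cell genes in 12 of 12 members, at -0.62 (-0.68 to -0.50), with Dapl1 at 0.302-fold and the transcription factor Lef1 at 0.538-fold. Ribosomal protein genes stood at -0.11 and mitochondrially encoded genes at -0.12. Smaller still were NF-kB targets (0.02), inflammatory cytokines and receptors (0.10), autophagy (0.11), fatty acid oxidation (0.06), DNA repair (0.09), TGF-beta (-0.09) and chromatin enzymes (-0.02). Immunoglobulin constant genes had a median of -0.26 but a mean of 0.12.

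The single genes furthest apart over all spleen cells mostly came from few cells. Matn1 (ENSMUSG00000040533, chromosome 4, 130944385 to 130955475) encodes a cartilage matrix protein and was highest in plasma cells. It had 8 vehicle UMIs and 401 MDL-800 UMIs, a 49.3-fold difference (24.8 to 115), in 7 and 38 cells. Olfm4, a protein of neutrophil granules, was 22.3-fold higher (12.6 to 43.7), and Stfa2, a cathepsin inhibitor, 30.2-fold (11.5 to 113), with 31.7% of its MDL-800 UMIs in 1 cell. Car1 had 0 and 165 UMIs (at least 54.1-fold), all in 1 cell, and Slc25a21 0 and 112 UMIs (at least 36.7-fold), of which 84.8% were in 1 cell. Lowest was the basophil protease Prss34, with 236 and 1 UMIs (vehicle 240-fold higher, 42.7 to 9518), and 98.7% of the vehicle UMIs were in 1 cell. Mcpt8, from the same kind of cell, was 0.197-fold (0.136 to 0.279), with 98.5% of its vehicle UMIs in 1 cell. Nbea (0.187-fold, 0.102 to 0.322), Dlg5 (0.201-fold, 0.112 to 0.342) and Tdrp (0.253-fold, 0.161 to 0.386) completed the lowest, and Tdrp was spread over 93 vehicle and 26 MDL-800 cells.

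B cells of the MDL-800 spleen library had higher levels of cell division, chaperone and interferon genes and lower levels of early response genes. Cell cycle genes stood at a median log2 fold of 1.19 (1.09 to 1.31), higher in 29 of 29, with Cdk1 at 3.82-fold (2.86 to 5.18) and the spindle protein gene Tpx2 at 3.63-fold (2.70 to 4.94). A small cycling B cluster (0.715% and 1.24% of cells) was larger in that library. Heat shock genes were higher in 14 of 14, at 0.44 (0.42 to 0.50), led by Hspa1a (1.89-fold) and Hspa1b (1.74-fold), near-identical copies. Interferon response genes stood at 0.34 (0.23 to 0.44), with Rsad2, an antiviral enzyme, at 3.60-fold (1.90 to 7.29). MHC class I genes, which show peptides to CD8 T cells, stood at 0.23 in 13 of 13, led by the peptide pump Tap1 (1.45-fold). OXPHOS genes encoded in the nucleus stood at 0.22 (69 of 75 higher), antioxidant genes at 0.30, ribosomal protein genes at 0.12 and DNA repair at 0.30, which was -0.01 in cells thinned to 1000 UMIs. Immediate early genes, switched on within minutes of stimulation, were lower in 17 of 19, at -0.29 (-0.36 to -0.22), with Klf4 at 0.544-fold and Klf6 at 0.680-fold. Age-associated B cell genes were lower in 12 of 15, at -0.29 (-0.40 to -0.21), with Adgre1 at 0.292-fold and Ahnak at 0.421-fold, while Fcrl5 was 1.43-fold higher. The cluster with Sox5 and Bhlhe41 was 322 of 2362 vehicle and 122 of 1590 MDL-800 B cells, so the make-up of the class differed too. Adgre1 in B cells was 6.46% of its level in macrophages.

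The B cell genes furthest apart were found in few cells of the class. Fat3, a large cadherin gene, was 23.2-fold higher (10.4 to 64.4) in 6 and 42 cells, and Greb1l 22.2-fold (9.20 to 69.8) in 5 and 31 cells. Both were leading genes of 1 small B cell cluster, with a UMI in 49.4% and 29.6% of its cells. Nhsl1 had 2 and 101 UMIs, a 54.9-fold difference (14.8 to 460), in 2 and 41 cells. Fat3 and Nhsl1 are long genes (591 kb and 215 kb on GRCm38), and reads in introns were counted. Matn1 was 24.1-fold higher (10.8 to 66.9) at 7.99% of its plasma cell level, and Slc25a21 was at least 40.6-fold higher. Ndnf, a secreted protein gene, had 142 and 24 UMIs (vehicle 5.44-fold higher), in 97 and 19 cells. Hcrtr2, a receptor gene detected in 25.9% of the cluster with Bhlhe41 and Sox5, was 0.316-fold (0.247 to 0.402). Tanc2 was 0.300-fold (0.224 to 0.396), Otx2os1 0.266-fold (0.177 to 0.389) and Ighg1 0.273-fold (0.195 to 0.377), the last at 0.814% of its plasma cell level.

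Cells of the T cell class in the MDL-800 spleen library had lower levels of genes of naive cells, those that have not met their antigen, and higher levels of activation genes. The class leaves out the unnamed clusters with T cell genes. The largest of these, with Ccl5 in 100%, Samd3 in 64.1%, Ctla2a in 91.3% and Eomes in 51.6% of its cells, was the one at 6.31% and 1.78%, so the activation genes are given for the named class only. Over all spleen cells the activated and exhausted list stood at -0.01. The naive list was lower in 11 of 12, at -0.43 (-0.52 to -0.37), with Dapl1 at 0.341-fold (0.273 to 0.423) and Igfbp4 at 0.358-fold (0.240 to 0.523). The cluster led by Dapl1 and Lef1 was 219 of 774 vehicle and 128 of 589 MDL-800 cells of the class. The make-up of the class thus differed too, and levels within cells were not told apart from it. Activated and exhausted genes were higher in 17 of 19, at 0.26 (0.20 to 0.35), with Eomes, a transcription factor of memory and killer cells, at 2.56-fold (1.92 to 3.45). NF-kB targets were higher in 19 of 21, at 0.35 (0.19 to 0.44), with the adhesion gene Icam1 at 1.63-fold (1.30 to 2.04) and the chemokine Ccl4 at 6.18-fold (3.01 to 14.3), of whose 9 vehicle UMIs 77.8% were in 1 cell. Interferon genes stood at 0.43 (0.25 to 0.50) and included Rtp4 (2.31-fold) and Isg15 (1.95-fold), inflammatory cytokines and receptors at 0.31 (0.06 to 0.58), MHC class I at 0.17 and cell cycle at 0.23, which was -0.01 in thinned cells. The lipid carrier gene Osbpl6 was 18.8-fold higher (9.26 to 44.4), in 5 and 55 cells. Samd3 was 4.10-fold, Ctla2a 3.80-fold and Lrmda 3.34-fold higher, and 46.7% of the MDL-800 UMIs of Lrmda came from 1 cell. Prss12 (0.297-fold, 0.181 to 0.470), St8sia6 (0.404-fold, 0.300 to 0.538) and Cd55 (0.455-fold, 0.329 to 0.621) were lower.

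Spleen monocytes had lower genes of MHC class II, the molecules that present antigen to CD4 T cells. All 8 measured class II genes were lower in the MDL-800 library, with a median log2 fold of -1.18 (-1.42 to -0.97). H2-Eb1 was 0.308-fold (0.264 to 0.359) and H2-Aa 0.335-fold (0.294 to 0.380), at 6.61% and 9.09% of their levels in dendritic cells. Class II genes were lower in spleen mature neutrophils as well. For monocytes, other cells joined to those of the vehicle set are thus not excluded. Free RNA of the shared run would reach both libraries alike, and median depth was 6631.5 UMIs per vehicle and 5997 per MDL-800 monocyte. Over all spleen cells the class II list stood at -0.27, lower in 10 of 10, with its transcriptional switch Ciita at 0.795-fold (0.754 to 0.839). Immediate early genes of monocytes were lower in 16 of 18, at -0.46 (-0.57 to -0.37), with Atf3 at 0.391-fold (0.323 to 0.472). Cell cycle genes stood at 0.51 (0.43 to 0.88), granule genes at 0.43, interferon genes at 0.29 (0.08 to 0.39) and heat shock at 0.23.

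The spleen neutrophil lineage as a whole compared mostly mature vehicle cells (197 of 223) with a MDL-800 class in which precursors were 209 of 387 cells. TMM scaling moved the median of all its genes by 0.34 log2, so the lists are given after it. Cell cycle genes stood at 1.36 (28 of 29 higher), granule genes at 1.25 and OXPHOS at 0.66. Maturation genes stood at -0.90, with the decoy receptor Il1r2 at 0.278-fold on totals, inflammatory genes at -0.90, immediate early genes at -0.88, NF-kB targets at -0.59 and interferon genes at -0.34. The ribosomal list was 0.26 after TMM and -0.09 on totals. Histone genes Hist1h2an (11.2-fold, 3.75 to 55.2) and Hist1h2bm (7.61-fold, 2.89 to 28.4), Stfa2 (11.0-fold, 3.69 to 54.3), Olfm4 (9.09-fold, 4.55 to 21.3) and Stfa1 (7.17-fold, 4.85 to 11.1) were highest. Lowest were the B cell and class II genes Bach2 (0.115-fold), Aff3 (0.136-fold), Cd74 (0.155-fold), H2-Aa (0.159-fold) and H2-Ab1 (0.189-fold). These stood at 0.928% to 3.18% of their level in the highest class, so free RNA or joined cells are not excluded as their source.

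Mature neutrophils alone, 197 and 178 spleen cells, had higher interferon response genes in the MDL-800 library. The list stood at 0.53 (0.14 to 0.79), with 11 of 17 members higher. Ifi27l2a, an interferon-induced gene of the mitochondrial membrane (ENSMUSG00000079017, chromosome 12, 103442167 to 103443680), had 63 and 290 UMIs in 22 and 65 cells, a 4.63-fold difference (3.52 to 6.19). Rtp4, another antiviral gene, was 3.10-fold higher (1.95 to 5.08). Ribosomal protein genes were lower in 74 of 78, at -0.35 (-0.42 to -0.30), although pairs of tags ranged from -0.72 to 0.04. The 5 lowest genes were Rpl10a (0.417-fold), with 51.2% of its vehicle UMIs in 1 cell, and B cell and class II genes. Those were Bach2 (0.209-fold), H2-Aa (0.339-fold), Cd74 (0.351-fold) and Mef2c (0.372-fold). B cells joined to vehicle neutrophils are thus not excluded for these or for the ribosomal list. Free RNA of the shared run would reach both libraries alike, and median depth was 2552 UMIs per vehicle and 2879.5 per MDL-800 cell. Mitochondrially encoded genes stood at 0.45 and MHC class I at 0.28.

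Bone marrow was compared in the same way, as the organ in which these cells are made. The B lineage was a smaller share of the MDL-800 library at every stage, and myeloid progenitors a larger one. B cells were 6.04% (5.37% to 6.76%) of vehicle and 1.82% (1.44% to 2.26%) of MDL-800 cells, 282 and 77 cells, 3.32-fold more in the vehicle library. B cell precursors, which are assembling their antibody genes, were 1.71% and 0.684%, a difference of -1.03 percentage points (-1.49 to -0.581) that was -0.359 from markers alone. Plasma cells were 0.706% and 0.283%, on 33 and 12 cells. T cells were 3.36% and 1.96%, a difference of -1.40 percentage points (-2.07 to -0.737) that was -0.607 with all 4 libraries clustered together. Plasmacytoid dendritic cells, the main source of type I interferon, were 0.664% and 0.330%, but the MDL-800 tags stood at 0.0524% and 0.558% and the lower vehicle tag at 0.562%, so that difference rests on 1 tag. Granulocyte-monocyte progenitors, which give rise to neutrophils and monocytes, were 5.18% and 7.45%, a difference of 2.27 percentage points (1.26 to 3.30) that was 1.20 without Scrublet calls and 3.63 in thinned cells. An unnamed cluster with Elane in 77.8% of its cells and Nrg1 in 69.3% was 3.83% and 6.06%, and unnamed cells together differed by 0.450 percentage points with the stricter filter and by -0.218 from markers alone. Stem and progenitor cells (1.95% and 2.45%), erythroid cells (1.82% and 1.58%) and monocytes (5.84% and 6.82%) had intervals of the difference that held 0. For monocytes that depended on the setting: the difference was 0.973 percentage points, but 2.62 (1.39 to 3.86) without a cell filter, 2.85 (1.60 to 4.10) with the stricter filter, 3.42 (2.24 to 4.61) at Leiden resolution 2 and 2.51 (1.25 to 3.77) in thinned cells.

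The neutrophil lineage made up 68.9% and 70.6% of bone marrow cells, a difference of 1.67 percentage points (-0.245 to 3.57) that was -1.06 without the cell filter. Within it the balance differed. Precursor clusters were 27.6% of vehicle and 33.0% of MDL-800 cells, a difference of 5.40 percentage points (3.49 to 7.31) that was 3.46 without the cell filter, and mature clusters 41.3% and 37.6%, a difference of -3.74 (-5.76 to -1.71). A mature cluster with Clec4d, Acod1 and the cytokine gene Osm was 11.0% and 6.11%. Another, with the cathepsin inhibitors Cstdc4 and Stfa2l1, was 8.73% and 12.3%, and had Clec4d (73.5%) and Acod1 (31.1%) in as many of its cells as the first (75.2% and 29.8%). The line between these clusters depended on the clustering, and each was not found again under 5 of the alternatives.

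Sirt6 had 68 and 99 UMIs over all bone marrow cells, or 2.93 and 3.45 UMIs per 1000000, and a fold of 1.18 (0.856 to 1.63). In the neutrophil lineage the fold was 1.26 (0.723 to 2.25) and in granulocyte-monocyte progenitors 1.48 (0.569 to 4.30). No difference was detectable in any of these. For bone marrow, list medians over all cells, progenitors and neutrophil classes are given after TMM scaling. It moved the median of all genes by 0.12 log2 over all cells, 0.12 in granulocyte-monocyte progenitors, 0.14 in the neutrophil lineage and 0.16 in mature neutrophils.

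Over all bone marrow cells, B and T cell genes were lower in the MDL-800 library and granule genes higher, as the shares of these cells were. Class II genes stood at -1.51 (0 of 10 higher), with Ciita at 0.202-fold (0.158 to 0.255) and H2-Ob at 0.291-fold (0.233 to 0.362). Immunoglobulin constant genes stood at -1.65, with Ighg2b at 0.0451-fold, although 53.7% of its vehicle UMIs came from 1 cell. Naive T cell genes stood at -1.06, with the lymph node homing receptor Ccr7 at 0.178-fold and S1pr1 at 0.235-fold, and activated T cell genes at -0.57. Age-associated B cell genes stood at -0.26. Immediate early genes were lower in 18 of 19, at -0.47, with Atf3 at 0.406-fold (0.357 to 0.461) and Fosb at 0.471-fold (0.434 to 0.510). The senescence list stood at -0.25, with the growth factor Csf1 at 0.469-fold. Granule genes stood at 0.42, led by the proteases Ctsg (1.32-fold) and Prtn3 (1.32-fold), interferon genes at 0.24, glycolysis at 0.22, OXPHOS and ribosomal genes each at 0.18 and cell cycle at 0.16. Autophagy (0.15), antioxidant (0.16), DNA repair (-0.03), heat shock (-0.05), TGF-beta (-0.09), NF-kB (-0.16), inflammatory (-0.14) and maturation genes (-0.06) lay closer to 0. Sirtuins (0.10 after TMM, -0.02 on totals), MHC class I (0.08 and -0.04), mitochondrially encoded genes (0.04 and -0.08) and fatty acid oxidation (0.11 and -0.01) took their sign from the scaling.

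The genes furthest apart over all bone marrow cells again included genes of rare cells. Pf4, the main platelet chemokine (ENSMUSG00000029373, chromosome 5, 90772435 to 90773383), had 1320 and 5719 UMIs, a 3.51-fold difference (3.30 to 3.72), and Treml1, a platelet receptor, was 5.16-fold higher (3.03 to 9.36). Platelet gene UMIs came almost wholly from 7 vehicle and 11 MDL-800 cells. Pde3a was 9.41-fold higher (5.64 to 16.8) on 6 and 15 cells, Negr1 3.81-fold (2.71 to 5.47), and the eosinophil gene Prg2 5.16-fold (4.01 to 6.73), with 87.2% of its MDL-800 UMIs in 1 cell. Lower were Dmd (vehicle 16.1-fold higher, in 33 and 16 cells), the dendritic cell lectin Cd209a (11.1-fold, in 33 and 10 cells), Grm8 (0.128-fold), Dnm3 (0.139-fold) and Agbl1 (0.145-fold).

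Bone marrow neutrophils of the MDL-800 library had higher interferon response genes, and their lowest genes included Thbs1 and Ptgs2. The interferon list was higher in 22 of 23 members, at a median log2 fold of 0.71 after TMM and 0.57 (0.37 to 0.82) on totals. Ifi27l2a had 411 and 2203 UMIs in 214 and 692 cells, a 4.14-fold difference (3.72 to 4.61), Oas1a was 5.40-fold higher (2.67 to 12.4) and Rtp4 2.55-fold (2.11 to 3.09). Cd38, an enzyme that breaks down NAD and so competes with sirtuins for it, was 3.05-fold higher (2.15 to 4.41), in 37 and 131 cells. The cathepsin inhibitors Stfa2 (2.82-fold, 2.53 to 3.14) and Cstdc5 (2.52-fold, 2.30 to 2.76) were also higher. Thbs1, an adhesive glycoprotein that activates TGF-beta (ENSMUSG00000040152, chromosome 2, 118111876 to 118127133), had 1441 and 423 UMIs, 4.41-fold more in the vehicle library, in 564 and 226 cells. Ptgs2, which encodes the inducible prostaglandin enzyme COX-2 (ENSMUSG00000032487), was 2.92-fold higher in the vehicle library. The noncoding gene Ptgs2os2, which lies nearby on the other strand, was 0.360-fold (0.281 to 0.460), Slx1b 0.353-fold and the chemokine Ccl4 0.276-fold (0.187 to 0.399). Precursors were 1288 of 3219 vehicle and 1398 of 2992 MDL-800 cells of the lineage, so the make-up of this class differed too. Ribosomal protein genes of the lineage were higher in 78 of 78, at 0.54 (0.39 on totals and 0.33 in thinned cells), led by Rpl10a (1.65-fold) and Rpsa (1.63-fold). In mature neutrophils alone the ribosomal list stood at 0.075 on totals. OXPHOS genes stood at 0.25, cell cycle and granule genes each at 0.30, glycolysis at 0.23 and MHC class I at 0.20. Immediate early genes stood at -0.47, with Atf3 at 0.398-fold and Nr4a1 at 0.439-fold. The senescence list stood at -0.31, with Csf1 at 0.413-fold and the urokinase receptor Plaur at 0.564-fold, and inflammatory genes at -0.20, with Il1r2 at 0.462-fold.

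Among the pooled bone marrow classes, the interferon difference was widest in mature neutrophils, where 23 of 23 members were higher, at 1.04 after TMM and 0.88 (0.62 to 1.16) on totals. There Ifi27l2a was 5.00-fold higher (4.46 to 5.61) and Zbp1, a sensor of viral nucleic acid, 3.15-fold (2.28 to 4.43). Precursors stood at 0.75 after TMM, but their clusters differed, with 0.96 and 0.40 on totals in a pair of them and -0.05 (-0.20 to 0.30) in the one left. DNA repair genes of mature neutrophils stood at -0.40 and glycolysis at 0.37. The inhibitor Stfa2 was 3.37-fold higher (3.02 to 3.76) in them and Thbs1 0.254-fold.

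**Figure D2:**
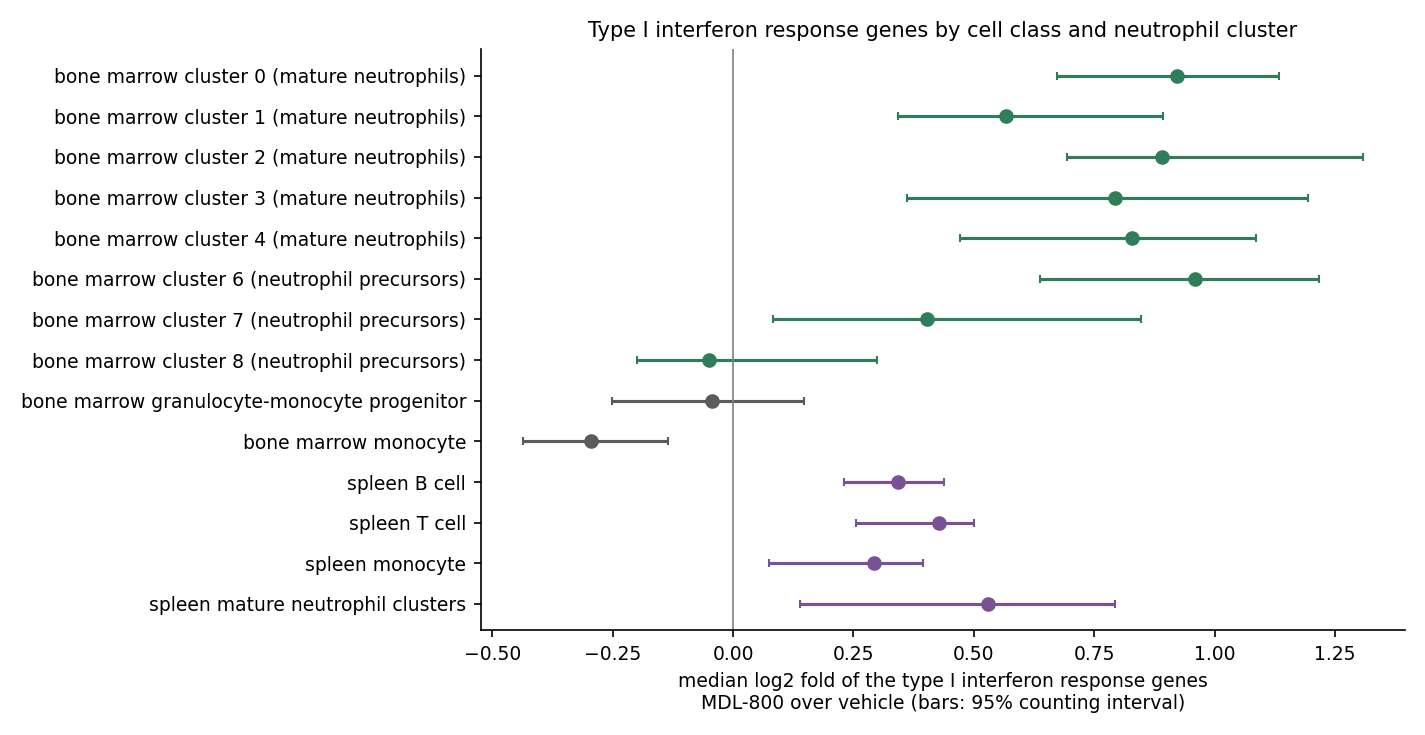
Median log2 fold of type I interferon response genes, MDL-800 over vehicle on totals, in each bone marrow neutrophil cluster and in other classes of both tissues, with 95% counting intervals as bars. Of 8 bone marrow neutrophil clusters, 7 stand between 0.40 and 0.96, while a precursor cluster stands at -0.05 and bone marrow monocytes at -0.29.

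Bone marrow monocytes, like those of the spleen, had lower class II and immediate early genes in the MDL-800 library. Class II stood at -1.36 (-1.44 to -1.25), lower in 7 of 7, with Ciita (ENSMUSG00000022504, chromosome 16) 3.67-fold higher in the vehicle library and Cd74, the chain that guides class II to its peptides, at 0.369-fold (0.347 to 0.393). Cd74 in monocytes was 24.0% of its level in B cells. The dendritic cell genes Cd209a (111 and 8 UMIs) and Clec10a (70 and 33 UMIs), chosen after their values were seen, were lower in this class as well. No cluster of bone marrow was named conventional dendritic cells, so a few such cells within the monocyte class are not excluded as the source. A cluster of the class had H2-Aa, H2-Eb1 and H2-Ab1 among its leading genes. It held 102 of 273 vehicle and 99 of 289 MDL-800 monocytes. At Leiden resolution 2 its nearest match was 0.985% and 1.67% of the libraries, against 2.18% and 2.33% here. The make-up of the class thus depended on the clustering, and levels within cells were not told apart from it. Immediate early genes stood at -0.61 (-0.79 to -0.56), with Atf3 at 0.318-fold (0.251 to 0.400) and the phosphatase Dusp1 at 0.314-fold (0.240 to 0.409). Interferon genes stood at -0.29 (-0.44 to -0.13), lower in 20 of 26, with Irf9 at 0.637-fold and Oasl2 at 0.640-fold. The median for cell cycle genes was -0.30 (-0.43 to -0.02), and 0.07 in thinned cells, and the histone genes Hist1h1b and Hist1h1d were 0.264-fold and 0.316-fold. Higher were the antibody receptor Fcgr4 (2.72-fold, 2.00 to 3.75, in 33 and 71 cells) and Tcf7l2 (2.55-fold, 1.83 to 3.60), genes of patrolling monocytes, with Negr1 (3.98-fold), Cadm1 (2.72-fold) and Acp5 (10.4-fold, 53.1% of MDL-800 UMIs in 1 cell).

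Granulocyte-monocyte progenitors differed chiefly in early response genes, which were higher in 2 of 18 members, at -0.62 after TMM. The list was lower in bone marrow neutrophils, in spleen B cells and in monocytes of both tissues too, so this was not particular to progenitors. Its cause was not tested. Fosb, a partner in the AP-1 transcription factor, had 186 and 54 UMIs, 4.98-fold more in the vehicle library, and Dusp1 (0.367-fold, 0.297 to 0.453), Plk3 (0.356-fold, 0.233 to 0.536), Hist1h2bl (0.383-fold) and Hist1h2ac (0.386-fold) were lower too. Granule genes stood at 0.33, autophagy at 0.23 and OXPHOS at 0.17. The interferon list was 0.08 after TMM and -0.04 on totals. The chaperones Hspa1a and Hspa1b (each 2.32-fold), the inhibitory receptor Siglece (2.23-fold), Ifitm6 (2.18-fold) and Olfm4 (2.17-fold) were higher.

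Y-linked genes were found in every library, as a check on the animals. The Y-linked genes Ddx3y and Eif2s3y were 0.965-fold (0.890 to 1.05) and 0.962-fold (0.881 to 1.05) in spleen and 0.818-fold and 0.791-fold in bone marrow, and Xist had at most 4 UMIs in a library. The sex-linked list stood at -0.22 in spleen and, after TMM, at -0.17 in bone marrow. Hemoglobin and red cell genes stood at 5.73 in spleen, where 4 MDL-800 cells held 97.7% of the hemoglobin UMIs, and at -0.15 after TMM in bone marrow, where each cell weighted equally gave 0.10 and thinned cells 0.21.

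Set side by side, both tissues had a smaller share of B cells and a larger share of neutrophil precursors in the MDL-800 library, but plasma cells stood in opposite directions, though under the stricter filter the interval for spleen held 0. Of the 28 lists, 18 had the same sign in both tissues over all cells on totals and 16 after TMM. Monocytes shared the sign in 18 of 25 lists (19 after TMM) and mature neutrophils in 14 of 24 (12 after TMM). Class II and immediate early genes were lower in monocytes of both tissues, and interferon genes were higher in mature neutrophils of both. For class II, other cells, within the class or joined to its cells, are not excluded as the source in either tissue. Interferon genes of monocytes stood at 0.29 in spleen and -0.29 in bone marrow. Differences between the tissues were not tested, since each rests on 1 library per treatment.

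**Figure D3:**
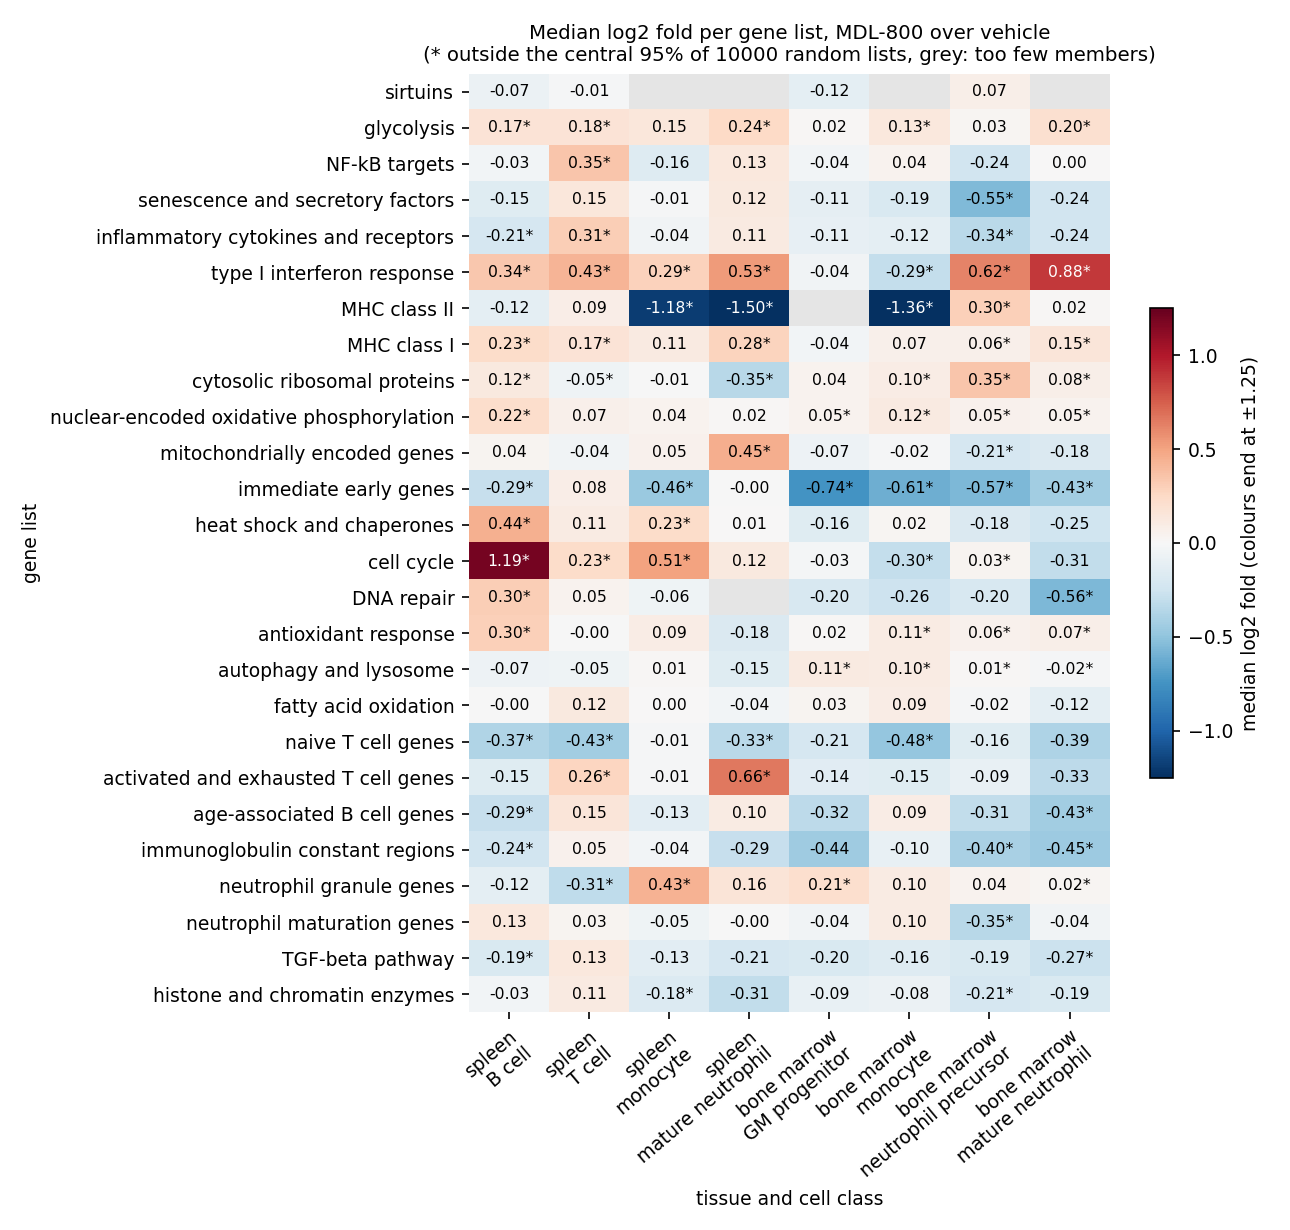
Median log2 fold of each gene list, MDL-800 over vehicle on totals, by tissue and cell class, with a star where it lay outside the central 95% of 10000 random lists and grey where too few members were measured. Class II is blue in monocytes (-1.18 in spleen, -1.36 in bone marrow) and spleen mature neutrophils (-1.50), and the highest interferon value is that of bone marrow mature neutrophils (0.88); the granulocyte-monocyte progenitor value of -0.04 for interferon genes turns to 0.08 after TMM.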

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

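The tests of bone marrow admixture in spleen and of the make-up of neutrophil clusters were chosen before their results were seen, and all other tests of the patterns weighed here after.

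Neutrophil precursors were 0.641% of the vehicle and 6.63% of the MDL-800 spleen library. Bone marrow cells mixed into the spleen suspension would bring granulocyte-monocyte progenitors along. MDL-800 spleen had 0.0670 cells (0.0360 to 0.115) with at least 10 UMIs of Elane, Mpo, Prtn3 and Ctsg per precursor, against 0.437 (0.397 to 0.481) in MDL-800 bone marrow, which argues against it. Mature and immature cells entering together in marrow proportion would give 1.14 mature neutrophils per precursor, and the excess held 0.133 (-0.0441 to 0.314). With all 4 libraries clustered together it held more mature cells, 2.86 percentage points beside 3.81 for precursors, still fewer per precursor than in MDL-800 bone marrow (42.5% and 28.4% of cells). Depth and the cell filter are argued against by differences of 5.92 percentage points (5.06 to 6.86) in thinned cells and 4.58 (3.90 to 5.31) without a filter. Blood formation in the spleen would need progenitors as well, so the few cells with those genes do not favour it over admixture. There were 14 beside 209 precursors, 3 of them outside precursor clusters. Whether it took place, from MDL-800 or from an animal with infection or disease, was not tested. Entry of cells in another proportion was not tested either, and with 1 library per treatment these stay open.

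B cells and their precursors were smaller shares of the MDL-800 bone marrow library. Dilution by neutrophils would lower all other classes alike, but the B cell ratio was 0.346 (0.230 to 0.521, from an approximate interval of log ratios) of the erythroid ratio. Ratios of shares were 0.301 for B cells, 0.583 for T cells, 0.869 for erythroid cells and 1.44 for granulocyte-monocyte progenitors. The neutrophil lineage itself was 68.9% of vehicle and 70.6% of MDL-800 cells. Less blood in the marrow would spare precursors, which stay in the marrow, yet their ratio of shares was 0.399 (0.252 to 0.618). For B cells, the ratio relative to precursors was 0.753 (0.460 to 1.23), so less blood as part of their difference cannot be told apart, on 29 MDL-800 precursors. Thinned cells gave -3.99 percentage points (-4.79 to -3.21), against depth. Lower B cell formation with MDL-800 may be the reason, as may a difference between animals, and both stay untested.

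Interferon genes were higher in neutrophils of the MDL-800 bone marrow library. A different make-up of neutrophil clusters would leave medians near 0 within clusters, but 7 of 8 clusters had an interval above 0, with medians from -0.05 to 0.96. Free RNA would add the same UMIs to every cell of the run, whatever its depth. Both libraries shared that run, so it would add them to vehicle and MDL-800 cells alike, and comparing classes cannot test it. MDL-800 cells of the neutrophil lineage had 1.74 more UMIs of the list per cell than vehicle cells (1.57 to 1.91). Their median depth was 4158 UMIs, against 2889 in vehicle cells. Every other class had more such UMIs per cell as well, though most intervals held 0, and these counts are not scaled for depth. Granulocyte-monocyte progenitors stood at 0.224 (-0.204 to 0.651) and monocytes at 0.846 (-1.27 to 2.96). Monocytes had a median depth of 4606 UMIs in the vehicle and 5548 in the MDL-800 library. Scaled to totals, their list median was -0.29, and that of progenitors took its sign from the scaling. B cells stood at 0.845 (0.0274 to 1.66) and unnamed cells at 1.50 (0.376 to 2.63). With every cell thinned to 1000 UMIs, and so weighted alike, the list median was 0.69 (0.45 to 0.92). Thinning leaves the expected proportions of genes in a cell unchanged, so it cannot decide on depth as such. An interferon response to MDL-800 may explain it, as may an infection of an animal, and 1 library per treatment leaves both open.

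Some results stood in opposite directions in the 2 tissues, and none of these differences between tissues was tested. The plasma cell share differed by 1.57 percentage points (MDL-800 minus vehicle) in spleen and -0.423 in bone marrow, and the spleen interval held 0 with at least 500 genes and at most 5% mitochondrial UMIs (1.04, -0.0146 to 2.14). The median log2 fold on totals was 0.27 in spleen and -0.37 in bone marrow for the senescence list over all cells. Neutrophil maturation genes over all cells stood at 0.61 and -0.18, and hemoglobin genes at 5.73 and -0.27, the spleen value resting on 4 cells. The bone marrow hemoglobin value turned to 0.10 with each cell weighted equally and 0.21 in thinned cells, the direction of spleen. In monocytes, interferon genes stood at 0.29 and -0.29 and cell cycle genes at 0.51 and -0.30, the last of which turned to 0.070 in thinned cells. In the neutrophil lineage, interferon genes stood at -0.68 and 0.57, where the spleen class compared mostly mature vehicle cells with many MDL-800 precursors. Ribosomal genes of the neutrophil lineage stood at -0.086 and 0.39, and those of mature neutrophils at -0.35 and 0.075, and the spleen value for the lineage turned to 0.26 after TMM.

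Tags that belong to the other tissue's run were counted above the tags that no library used, which had 0 to 91 UMIs. CMO307, a bone marrow tag, had 1130 UMIs in the vehicle and 944 in the MDL-800 spleen library. CMO303, a spleen tag, had 21057 UMIs in the vehicle and 18450 in the MDL-800 bone marrow library, in 84.7% and 85.2% of cells, and the next spleen tag, CMO304, had 2693 and 2108. The source of these UMIs was not tested.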

How the results depend on the processing

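Leaving out Scrublet calls was chosen after seeing the data, and the other alternatives before. A value counts as reversed where its interval excluded 0 and its sign turned. A list median also had to lie outside the central range of the random lists. Sign turns of other list medians are therefore not counted as reversals. Of 174 class shares recomputed, 145 stayed within their intervals, 28 moved beyond them and 1 reversed. Of 582 folds of named genes, 490 stayed, 92 moved and 0 reversed. Of 2771 list medians, 2186 stayed, 568 moved and 17 reversed. Keeping Scrublet calls was the same as the values reported, since none were removed. No paired analysis was possible within a tissue because its shared droplet run gives 1 pair of libraries and no label pairs the tags. A fit with the tissue as a block was not run. Except where the construction of the alternative is named, the cause was not tested.

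Without a cell filter, differences in share (MDL-800 minus vehicle, percentage points) were -3.86 for spleen B cells, 4.87 for the spleen neutrophil lineage, 4.58 for spleen precursors, 2.62 for bone marrow monocytes, -1.06 for the bone marrow neutrophil lineage and 3.46 for bone marrow precursors. With at least 500 genes and at most 5% mitochondrial UMIs, they were -3.03 for spleen T cells, -3.31 for bone marrow B cells and 2.85 for bone marrow monocytes. In cells thinned to 1000 UMIs they were -3.77 for spleen T cells, 3.63 for granulocyte-monocyte progenitors and 2.51 for bone marrow monocytes. Classes from markers alone gave -4.05 for spleen T cells, -0.359 for B cell precursors and a reversed -0.218 for unnamed bone marrow cells, since that setting forms no clusters. Leiden resolution 2 gave 5.14 for the spleen neutrophil lineage, 4.34 for spleen precursors and 3.42 for bone marrow monocytes. All 4 libraries clustered together gave 3.81 for spleen precursors and -0.607 for bone marrow T cells. Leaving out Scrublet calls gave 1.20 for granulocyte-monocyte progenitors.

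Over all spleen cells, list medians in thinned cells were 0.40 for interferon, -0.21 for class II, 0.80 for cell cycle and 1.50 for granule genes. With each cell weighted equally they were -0.19 for class II, 0.78 for cell cycle and 1.36 for granule genes. Class II was -0.24 with TMM and -0.24 with median of ratios. Immunoglobulin constant genes reversed to 0.12 as a mean, 0.036 with equal weights and 0.035 in thinned cells. In spleen B cells, the mean reversed to 0.28 for inflammatory genes and 0.025 for TGF-beta, and thinning reversed DNA repair to -0.011. In spleen T cells, thinning reversed cell cycle to -0.015, and naive T cell genes were -0.55 as a mean and -0.54 in thinned cells. In the spleen neutrophil lineage, the mean reversed glycolysis to -0.028. Ribosomal genes there reversed to 0.26 with TMM, 0.22 with median of ratios, 0.18 with equal weights, 0.11 in thinned cells and 0.018 without Scrublet calls. Activated T cell genes of spleen mature neutrophils reversed to -0.040 without Scrublet calls.

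Over all bone marrow cells, class II was -1.51 with TMM, -1.50 with median of ratios, -1.42 as a mean, -1.38 with equal weights and -1.36 in thinned cells. Immediate early genes were -0.47, -0.46, -0.56 with equal weights and -0.54 in thinned cells, the first pair with TMM and median of ratios. Immunoglobulin constant genes were -1.65 with TMM, -1.64 with median of ratios, -1.96 as a mean, -1.49 with equal weights and -1.39 in thinned cells. Hemoglobin genes reversed to 0.10 with equal weights and 0.21 in thinned cells, and cell cycle genes of monocytes to 0.070 in thinned cells. Ribosomal genes of the neutrophil lineage were 0.54 with TMM, 0.53 with median of ratios, 0.33 with equal weights and 0.33 in thinned cells.

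Which genes were furthest apart depended on the minimum count, since rarely counted genes reach wider folds, and also on depth and cell weights. In thinned cells 0 of 10 sets of named genes kept at least 2 of every 3 genes, and with each cell weighted equally 2 of 10 did. Of the 10 named genes, 3 were shared over all spleen cells with a minimum of 10 UMIs and 0 with 500, and 0 and 6 in the bone marrow neutrophil lineage. Some alternatives gave no value for some results. At least 500 UMIs left too few members of several lists, such as sirtuins. Thinned cells formed no unnamed class, and markers alone gave no precursor or mature clusters. With 1 library per group, depth limits only the counting error of each library.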

Other observations

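The spleen T cell clusters differed unevenly. The values in this part come with no test. Naive CD8 cells with Dapl1 and Lef1 were 5.40% of the vehicle and 4.06% of the MDL-800 library. The difference of -1.33 percentage points was -4.55 with at least 500 genes and at most 5% mitochondrial UMIs. A cluster with Foxp3, the master gene of regulatory T cells, among its leading genes was 10.2% and 10.5%. That difference of 0.331 percentage points was 1.45 (0.114 to 2.82) with all 4 libraries clustered together. The cluster held 413 of 774 vehicle and 331 of 589 MDL-800 cells of the T cell class. It was named T cell only, so its share is not that of regulatory T cells. The unnamed killer-receptor cluster had Cd8b1 in 79.8%, Ccl5 in 100% and Eomes in 51.6% of its cells, and Ncr1, a gene of natural killer cells, in 3.21%. Its tags stood at 6.28% and 6.34% in the vehicle library and 1.74% and 1.82% in the MDL-800 library. Another unnamed cluster, with Gzmk in 70.1% of its cells, was 2.37% and 3.21%. One more unnamed cluster, with Zbtb16 and Il4, held 16 cells in each library.

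Rare cells set several of the widest folds. Basophil genes had 477 UMIs in the vehicle spleen library, of which 97.1% were in 1 cell, and 94 in the MDL-800 library. In bone marrow they had 6243 UMIs, with 16 cells of at least 20 UMIs, in the vehicle library and 3795 UMIs and 12 such cells in the MDL-800 library. Platelet genes had 1345 UMIs in the vehicle and 5871 in the MDL-800 bone marrow library, 90.5% and 98.1% of them in 7 and 11 cells. The spleen count was 22 and 245 UMIs, with 63.3% of the latter in 1 cell. The bone marrow UMI totals of hemoglobin genes were alike, 43912 and 47987.

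The Xist antisense gene Tsix had 20 vehicle and 2 MDL-800 UMIs in spleen, and 40 and 6 in bone marrow. Tsix was chosen after its values were seen, and so were the platelet gene counts. Median depth also differed within classes. Erythroid cells had a median of 10819 UMIs in the vehicle and 3566 in the MDL-800 bone marrow library, the opposite order from most other classes.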
